A study of Mus musculus with 2 samples.

How the data were processed

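Single-cell RNA of mouse spleen germinal centre B cells was measured with 10x Genomics 3′ chemistry in 2 samples, pools 1 and 2, each a mixture of Irf4+/+ and Irf4+/- cells that form a single group. Per the labels, the authors aligned the reads to mm10 and counted them with Cell Ranger 3.1.0. The deposited matrices hold counts, whole UMI numbers per gene and barcode with no normalization, for barcodes that Cell Ranger called as cells. The other deposited files are lists of barcodes and of gene identifiers with no measured values. Of the features, 30934 were matched by identifier to the GENCODE M21 annotation, which gave positions. Only features of the gene expression type were present, 0 antibody features, so the planned comparison of genotypes could not be run, and Irf4 counts were not used in its place. The labels mention recipient mice without saying how these relate to the pools, so p-values measure the spread between these libraries only. Among the barcodes, 7 occur in both pools and were treated as separate cells.

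Depth was 7655209 UMIs over 3313 barcodes in pool 1 and 14342718 UMIs over 5047 barcodes in pool 2. Barcodes with at least 200 genes and at most 50% mitochondrial UMIs were kept. The limit chosen before the data were examined was 10%, as were the comparisons, markers, gene lists and most alternatives. A limit of 10% would have kept 638 of the 3313 barcodes and 277 of the 5047, so it was raised after seeing the data. At 50%, 20 and 7 barcodes had too few genes and 27 and 63 had too high a share, in pools 1 and 2. The doublet caller of scanpy 1.11.5 (Scrublet) called 0 doublets in both pools, so none were removed and keeping called doublets, an alternative chosen in advance, changed nothing. As an added alternative, the barcodes with the highest doublet scores were removed at 0.8% per 1000 barcodes.

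Counts were scaled to 10000 per cell and log-transformed, and 1000 variable genes, 30 principal components and 15 neighbours were used for Leiden clustering (igraph 0.11.9) at a resolution of 0.8. Immunoglobulin, mitochondrial, ribosomal, Y-linked and listed functional genes, as well as Xist, Tsix and Irf4, were kept out of the clustering. This gave 12 clusters, of which 1 was split again at a resolution of 0.5 with 15 components. Clusters were named from 11 lists of markers by log2 folds of summed CPM with an offset of 20 CPM. A cell type outside the germinal centre was named where at least 3 of its markers had a fold of at least 1 over all other cells and the mean of its list was at least 0.7. Of the rest, clusters whose mean over the pan-B markers was under −2 were left as unnamed other, and the others were compared with one another. The zone with more markers at a fold of at least 0.4, and at least 3, gave the name, and clusters with neither were left as unnamed germinal centre. The markers were fixed beforehand, but these thresholds were set after the marker folds of the clusters had been seen, before any comparison was fitted. In all, 7 clusters were taken as germinal centre. Isotypes were called in cells with at least 3 UMIs over the heavy chain constant genes, of which at least 70% were of a single isotype.

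Raw counts were summed per pool and class, for classes with at least 20 cells in each pool, and fitted in edgeR 4.0.16 (R 4.3.3) with TMM factors, filterByExpr, the quasi-likelihood F-test and the pool as a block. Genes used for clustering or naming were left out of the counts of differing genes. The other genes are still not independent of the classes, which were formed from the same cells and counts. The Benjamini-Hochberg adjusted p threshold was 0.05. Light zone-like cells were compared with dark zone-like cells, in a fit that also held the resting B cell-like and myeloid-like libraries. The standard errors between the zones thus also reflect the spread of those libraries, of 58 and 23 cells for the myeloid-like class. The comparison of resting B cell-like cells with the germinal centre classes, and that of a Bcl2a1-high cluster with other light zone-like cells, were added after the clusters were seen. The planned comparison of plasmablast-like cells was not run with the settings above, since pool 2 held 17 of them. For the comparison by Irf4 UMI, B lineage cells were thinned to 1500 UMIs, the 25th percentile rounded down, and shallower cells and Irf4 itself were left out. Standard errors come from the fitted log2 changes. The edgeR fit was tested on simulated counts for the same numbers of summed libraries, with a single dispersion for all genes. Of 67 genes changed 2-fold, 16 were called between the zones and 26 by Irf4 UMI. Of 66 genes changed 4-fold, 63 and 47 were called, with 2 and 0 false calls. Clustering, naming and thinning were not simulated, so these numbers do not cover false calls that arise from how the classes were formed.

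In all, 19 functional lists and 11 marker lists with 524 genes, of which 3 were absent from the data, were written before the data were examined. The functional lists were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the lists, and again with an estimated correlation and with fry, which tests whether the genes of a list move one way without comparing them to other genes. Genes are named by a fixed rule: the 10 largest rises and the 10 largest falls among genes past the threshold, of at least 50 CPM and of the same direction in both pools, leaving out immunoglobulin variable, predicted and mitochondrial genes, plus Irf4 and up to 4 members of at least 50 CPM per described list. Members outside that rule are stated as named after their values were seen. Shares carry exact Clopper-Pearson intervals, and shares of 0 the limit that 3 counts would give.

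Alternatives chosen in advance were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors, no filter on low counts, no pool block, leaving out each replicate, a mitochondrial limit of 5%, at least 500 genes per cell, resolutions of 0.5 and 1.2, cell cycle scores regressed out, each pool clustered on its own, thinning to 750 UMIs, no thinning, another thinning seed, light zone-like or dark zone-like cells only, at least 2 Irf4 UMIs without thinning, and other isotype minimums. Alternatives added after seeing the data were mitochondrial limits of 10% and 30%, removal of the highest doublet scores, zones without the Bcl2a1-high cluster, without the cycling dark zone-like clusters or fitted on their own libraries, germinal centre clusters only, mitochondrial and ribosomal RNA genes left out, and restrictions of the Bcl2a1-high comparison to barcodes of 2000 to 6000 UMIs or at most 15% mitochondrial UMIs. Clustering used single precision and approximate neighbours, and its classes were found to depend on the type of processor. Clustering with double precision and exact neighbours was therefore added as an alternative, and the regression of cell cycle scores used both too, a change made after its results had been seen to differ between machines. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.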

Results

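Single-cell RNA of spleen germinal centre B cells was measured on day 10 of an immune response in 2 pools, replicates 1 and 2 of a single group of mixed cells. The cells carried the SWHEL receptor, a knock-in antibody against hen egg lysozyme, and came from donors with both copies of Irf4 (Irf4+/+) or with a single copy (Irf4+/-), a transcription factor that acts in B cell activation and plasma cell formation. Donor cells were transferred at a ratio of 3:1, Irf4+/- to Irf4+/+, and equal numbers of both genotypes were then sorted into a shared tube as Fas-high, CD38-low, lysozyme-specific cells. Pool 1 held 3313 barcodes and 7655209 UMIs, with a median of 1838 UMIs and 887 genes per barcode. Pool 2 held 5047 barcodes and 14342718 UMIs, with medians of 2188 UMIs and 912 genes. After filtering, 3285 cells of pool 1 and 4983 of pool 2 were left, 8268 in all. Mitochondrial transcripts made up a median of 20.1% of the UMIs per barcode in pool 1 and 26.6% in pool 2, and the classes below differed in this share. Both pools hold both genotypes, and the feature tables hold 0 antibody tag features that could tell them apart. The comparison of Irf4+/- with Irf4+/+ cells was therefore not analysed here, and no cell was given a genotype. The comparisons below are between cell states within the pools, with n = 2 pools unless stated, and intervals of shares are exact 95% Clopper-Pearson intervals that cover counting error only.

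The first question was which cell states the sorted cells held. Dark zone-like cells, named by a marker list that holds Cxcr4 and cell division genes, made up 42.6% ± 2.37 of the cells (SD, n = 2). Light zone-like cells, named by a list that holds Cd83, Nfkbia, Bcl2a1b and other markers of receptor and CD40 activation, made up 31.8% ± 0.623. Unnamed germinal centre cells, which met neither naming rule, made up 16.1% ± 5.90. Cells like memory or resting B cells made up 3.94% ± 1.45, and plasmablast-like cells, with markers of antibody secretion, 0.521% ± 0.254. In the latter class, 10 of 15 myeloid and 4 of 10 erythroid markers were also raised, with mean log2 folds of 1.49 and 1.37 over those lists. The dark zone-like share was 40.9% (39.3% to 42.6%) in pool 1 and 44.3% (42.9% to 45.7%) in pool 2, a difference beyond counting error. The light zone-like share was 32.3% (30.7% to 33.9%) and 31.4% (30.1% to 32.7%). With each pool clustered on its own, the dark zone-like difference turned round, at 36.6% and 30.6%, and the light zone-like share was 29.6% and 42.9%. With at least 500 genes per cell, the dark zone-like share was 33.4% and 57.6%. The unnamed germinal centre share also differed beyond counting error, at 11.96% (10.9% to 13.1%) in pool 1 and 20.3% (19.2% to 21.5%) in pool 2, but this difference turned round with at least 500 genes per cell, at 22.0% and 1.39%, and with cell cycle scores regressed out, at 48.8% and 15.9%. The resting B cell-like share was 4.96% (4.24% to 5.76%) and 2.91% (2.46% to 3.42%). In pool 2 the class fell from 145 cells to 78 with the highest doublet scores removed and to 85 with double precision and exact neighbours in the clustering. Within the dark zone-like class, a cluster of 155 cells in pool 1 held 1138 cells in pool 2, and another held 521 and 72 cells. A further cluster of the class, with 597 and 777 cells, was named on 4 of 15 dark zone markers, while its mean log2 fold over that list was −0.48, below that of the other germinal centre cells. No test was run on these shares, since both pools belong to the same group. Shares of the zones moved with the clustering, and the dark zone-like share was 3.57% with a mitochondrial limit of 10% and 0% with a limit of 5%. With double precision and exact neighbours in the clustering, an alternative added after the results were seen, 1331 of 8268 cells (16.1%) fell in another class. The unnamed germinal centre class was a single cluster with median mitochondrial shares of 25.8% and 31.4% and medians of 1313 and 1791.5 UMIs in pools 1 and 2. Lars2, Gm26917, Gm42418, AY036118 and mt-Nd5 were among its highest genes relative to other cells, and whether it was a cell state or reflected RNA quality was not tested.

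**Figure D1:**
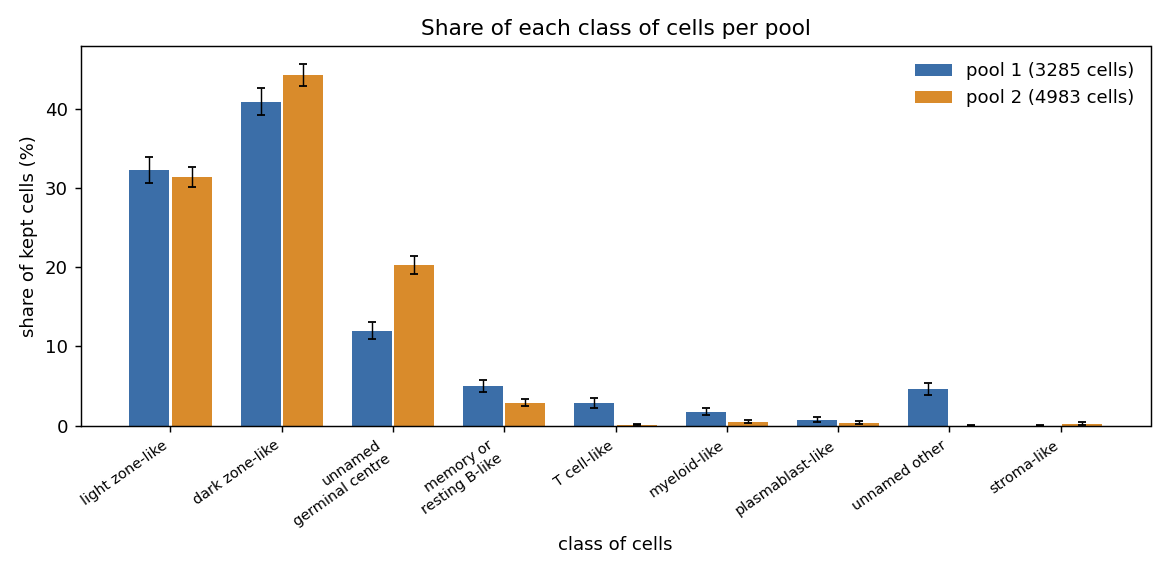
Share of kept cells (%) in each class, for pool 1 (3285 cells) and pool 2 (4983 cells), with bars for the share and error bars for the exact 95% interval. Dark zone-like cells were the most frequent class in both pools, at 40.9% and 44.3%, a difference that turned round with each pool clustered on its own. The unnamed germinal centre class differed most in percentage points, at 11.96% and 20.3%, a difference whose direction depended on the filter and the clustering. Rarer classes outside the germinal centre differed more as a ratio.

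The next question was which antibody classes the cells expressed, as class switching from Ighm to downstream constant genes marks antigen-experienced B cells. In the germinal centre clusters an isotype was called in 1587 of 2798 cells of pool 1 and in 2758 of 4783 cells of pool 2. Ighg1 was the most frequent, at 59.9% (57.5% to 62.3%) and 54.5% (52.6% to 56.3%) of called cells. Ighg2b followed at 31.6% (29.3% to 34.0%) and 32.0% (30.2% to 33.8%). Ighm was at 4.41% (3.45% to 5.54%) and 10.99% (9.84% to 12.2%), so that the unswitched share differed between the pools beyond counting error. Ighg2c was at 3.28% (2.46% to 4.27%) and 1.60% (1.16% to 2.14%). Ighg3 was at 0.441% and 0.653%, Ighe at 0.315% and 0.254%, and Igha at 0 of 1587 cells, which allows up to 0.189%, and 0.0725%. Ighd was called in 0 germinal centre cells of both pools, which allows up to 0.189% and 0.109% of called cells. Within the light zone-like class Ighm was at 4.79% and 14.1%, and within the dark zone-like class at 4.09% and 9.49%. In the resting B cell-like class Ighm was at 97.8% (92.3% to 99.7%) of 91 called cells in pool 1 and at 56.9% (44.0% to 69.2%) of 65 in pool 2. Of 163 and 145 cells of that class, 157 and 122 had at least 3 heavy chain UMIs, so many failed the purity rule. Ighd, at 579 CPM among the highest genes of that class, was called in 2 of 91 and 0 of 65 cells. A cell with both Ighm and Ighd can go uncalled, so these shares may understate Ighd and overstate switched isotypes. This was not tested. In pool 2, Ighg1 and Ighg2b were each called in 13 of 65 cells (11.1% to 31.8%) of that class, and in pool 1 both were at 0 of 91 cells, which allows up to 3.30%. Of the 92 T cell-like cells of pool 1, 16 also got an isotype call, 13 of them Ighm and 3 Ighg1, and whether this came from free RNA, doublets or the cells themselves was not tested. With a minimum of 10 heavy chain UMIs in place of 3, the mean Ighg2b share was 21.9% and the mean Ighg2c share 0.888%.

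**Figure D2:**
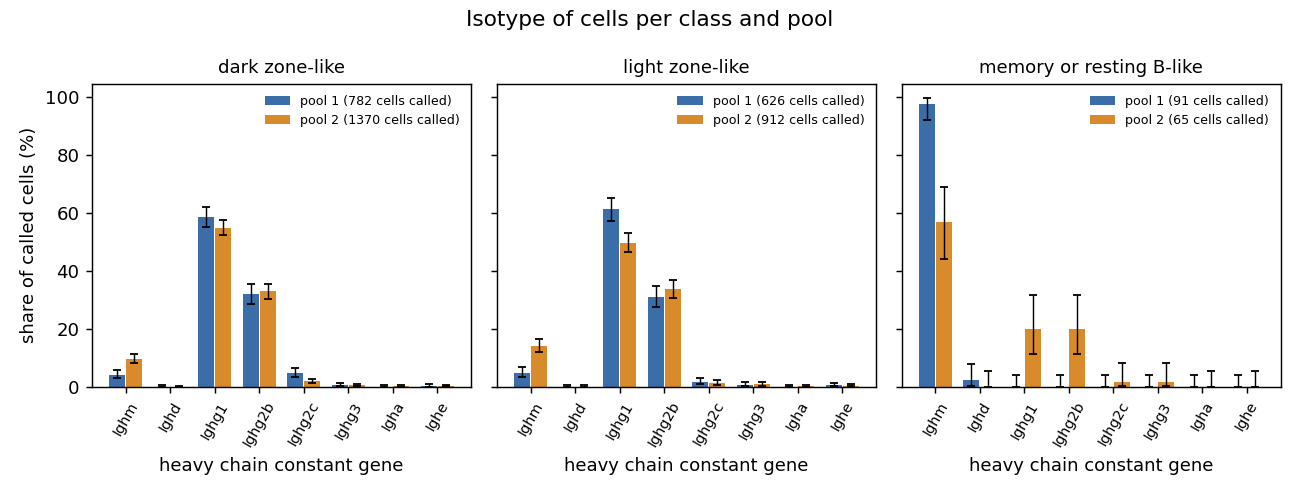
Share (%) of cells with a called isotype that expressed each heavy chain constant gene, per pool, in dark zone-like, light zone-like and memory or resting B cell-like cells, with exact 95% intervals as error bars. Ighg1 led in both zones and pools, and Ighm led in the resting B cell-like class, at 97.8% in pool 1 and 56.9% in pool 2.

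Light zone-like and dark zone-like cells were compared to describe the states between which germinal centre B cells cycle, selection in the light zone and division with mutation in the dark zone. Among the genes higher in light zone-like cells were C1qbp, a mitochondrial matrix protein, by 2.12 ± 0.34 on the log2 scale (SE, n = 2 pools), Npm1, a ribosome assembly factor, by 1.58 ± 0.39, Srm, spermidine synthase, by 1.5 ± 0.30, and Cd72, an inhibitory coreceptor of B cells, by 1.502 ± 0.32. Genes of cell division were lower: Esco2, which acetylates cohesin during replication, by −2.71 ± 0.33, Cit, a kinase of cytokinesis, by −2.60 ± 0.33, Cenpe and Cenpf, kinetochore proteins, by −2.52 ± 0.38 and −2.36 ± 0.37, and Kif11, a spindle motor, by −2.30 ± 0.32. The dark zone-like class was named in part by division markers, so the direction of the division genes was built into the classes. The light zone-like class was named by markers of receptor and CD40 activation, so the direction of the NF-kB and CD40 list below was built in as well. Erh (ENSMUSG00000021131, mm10 chromosome 12, 80634022 to 80644341, protein-coding) had the largest rise among genes of at least 50 CPM, by 2.16 ± 0.34 with an adjusted p of 3.67e-06 in edgeR. Esco2 (ENSMUSG00000022034, chromosome 14, 65819038 to 65833994, protein-coding) had the largest fall, with an adjusted p of 7.81e-09 in edgeR. Hspe1, Nme1, Cox5a, Eno1 and Rps27l also rose, by 1.53 to 1.82, and Ncapd2, Ube2c, Cdca8, Kif15 and Clspn also fell, by −2.03 to −1.90. Genes were named only where both pools agreed in direction, and the size differed between the pools: of 49 genes named between the zones, 22 moved by more than the SE without replicate 1 and 29 without replicate 2. Hspe1 was at 0.92 in pool 1 and 2.39 in pool 2, and C1qbp at 1.21 and 2.69. Of 8481 genes tested, 183 rose and 263 fell at an adjusted p under 0.05 in edgeR, and 1266 had an unadjusted p under 0.05. DESeq2 called 36 genes higher and 140 lower.

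Among the fixed gene lists, division genes fell together. Of 47 measured genes of the G2 and M phases, 36 fell and 0 rose, with 41 and 0 when adjusted over the list alone, and the median log2 change was −1.75. The camera test gave an adjusted p of 2.49e-29, and the call was lost at an adjusted p = 0.303 with an estimated correlation. Of 40 genes of the S phase, 12 fell, such as Pola1, the catalytic subunit of DNA polymerase alpha (−1.34 ± 0.30), and Uhrf1, which maintains DNA methylation (−1.19 ± 0.31), with 21 when adjusted over the list alone, a median of −0.71 and a camera adjusted p of 8.12e-16 (adjusted p = 0.303 with an estimated correlation). Of 15 genes of the NF-kB and CD40 response, Batf (2.21 ± 0.31), Ebi3 (2.27 ± 0.42), Nfkb2 (0.99 ± 0.29) and Bcl3 (0.92 ± 0.29) rose, members named after their values were seen, with 6 when adjusted over the list alone and a median of 0.69. That list had a camera adjusted p of 2.72e-07 and an adjusted p = 0.303 with an estimated correlation. Of 25 Myc target and ribosome biogenesis genes, 8 rose, among them Npm1, Srm, Nme1 (1.81 ± 0.35) and Hspe1 (1.82 ± 0.36), with 8 when adjusted over the list alone and a median of 0.54 (camera adjusted p of 1.33e-05; adjusted p = 0.547 with an estimated correlation). Of 25 genes of oxidative phosphorylation, 6 rose, such as Cox5a (1.67 ± 0.34) and Cox6c (1.31 ± 0.36), with 8 when adjusted over the list alone and a median of 0.41 (camera adjusted p of 0.00139; adjusted p = 0.736 with an estimated correlation). Of 20 genes of secretion and the unfolded protein response, Sdf2l1 (1.60 ± 0.32), Manf (1.26 ± 0.31), Sec61b (1.22 ± 0.35) and Spcs1 (1.05 ± 0.32) rose, of which Sdf2l1, Manf and Spcs1 were named after their values were seen, with 6 when adjusted over the list alone and a median of 0.32 (camera adjusted p of 1.33e-05; adjusted p = 0.303 with an estimated correlation).

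Antigen presentation genes shifted as lists without a single member past the test. Of 13 genes of MHC class II presentation, 0 passed and 0 when adjusted over the list alone, with a median of 0.45 and H2-Aa at 0.77 ± 0.40 (camera adjusted p of 4.23e-06; adjusted p = 0.303 with an estimated correlation). Of 13 genes of MHC class I presentation, 0 passed and 0 when adjusted over the list alone, with a median of 0.42 and Tapbp at 0.84 ± 0.31 (camera adjusted p of 6.28e-05; adjusted p = 0.382 with an estimated correlation). Of 24 cytosolic ribosomal protein genes, Rpl10 rose, by 1.47 ± 0.42, with 1 when adjusted over the list alone and a median of 0.39 (camera adjusted p of 4.23e-06; adjusted p = 0.642 with an estimated correlation). Of 18 genes of B cell receptor signalling, Cd72 rose, with 1 when adjusted over the list alone and a median of 0.15 (camera adjusted p of 0.0248; adjusted p = 0.642 with an estimated correlation). In this list the median was 0.34 in pool 1 and −0.0017 in pool 2. The other 9 of the 19 lists did not pass camera, at adjusted p-values from 0.180 to 0.866, and fry, run in place of camera, called 0 lists. Their members past the edgeR test, named after their values were seen, were Bid of 15 apoptosis regulators, Zeb2 and Batf of 18 germinal centre transcription factors, Eno1 of 14 glycolysis genes, Nr4a1 of 17 immediate early genes, Ifi203 of 15 interferon response genes, and Asns and Psph of 17 genes of mTORC1 and amino acid uptake, all higher. Of 18 genes of somatic hypermutation and repair, Apex1 rose and Polq and Lig4 fell, also named after their values were seen. Of 8 heat shock genes and 6 heavy chain constant genes, 0 passed, and in both lists the median (0.02 and −0.06) and the mean (−0.01 and 0.01) differed in sign. Adjusted over the list alone, the counts of higher and lower genes were 3 and 1 for apoptosis, 2 and 0 for transcription factors, 1 and 0 for glycolysis, 2 and 0 for immediate early genes, 2 and 0 for interferon response, 3 and 0 for mTORC1, 1 and 2 for hypermutation, and 0 for the last pair of lists.

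A cluster of the light zone-like class with high Bcl2a1b and Bcl2a1d, 33 cells in pool 1 and 250 in pool 2, changed the direction of several lists in this comparison. The cluster gave 206575 of the 1960004 UMIs summed for the class in pool 1 and 2195399 of 4604976 in pool 2. Without it, a choice made after seeing the data, the median log2 change of Myc target genes was −0.62, that of oxidative phosphorylation −0.82, that of ribosomal proteins −0.15 and that of secretion genes −0.15, while Npm1 was at −0.66 and Erh at −0.89. With cell cycle scores regressed out, in double precision and with exact neighbours, a form not chosen in advance, those medians were −0.46, −1.24, −0.45 and −0.21, with Npm1 at −1.70 and Erh at −2.45, and 215 cells of the cluster were named dark zone-like. With double precision and exact neighbours alone, 222 of its cells were named dark zone-like, the medians were −0.90, −1.13, −0.24 and −0.30, with Npm1 at −1.62 and Erh at −2.40, and 20 of the 49 named genes changed direction, so the reversal cannot be put down to the regression. The higher values of these 4 lists in light zone-like cells, and of the genes that reversed, thus held for the clustering used here and not for these alternatives. Both lists of antigen presentation kept their direction and their side of the threshold in all 3 of these alternatives. Without the cluster, 512 genes were higher and 863 lower. Without the cycling dark zone-like clusters, 56 genes were higher and 13 lower, and the median change of the G2 and M phase genes was 0.21.

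**Figure D3:**
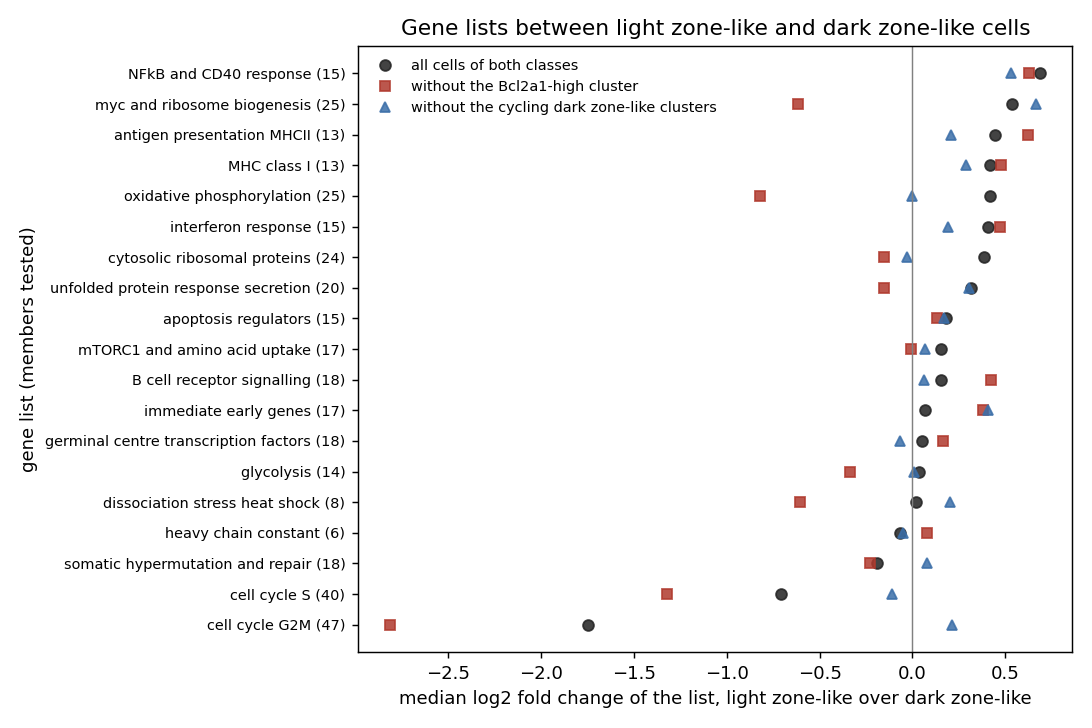
Median log2 fold change of each fixed gene list, light zone-like over dark zone-like, over all cells of both classes (circles), without the Bcl2a1-high cluster (squares) and without the cycling dark zone-like clusters (triangles), with the number of tested members in brackets. The median of the Myc list was 0.54 over all cells and −0.62 without the Bcl2a1-high cluster, and that of the G2 and M phase list was −1.75 over all cells and 0.21 without the cycling clusters.

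Irf4 (ENSMUSG00000021356, mm10 chromosome 13, 30749226 to 30766976, protein-coding) was the gene whose dose the donors differed in, and its level was compared between classes without regard to genotype. Light zone-like and dark zone-like cells did not differ detectably in Irf4, at a log2 change of 0.07 ± 0.29 (SE, n = 2 pools; 0.10 in pool 1 and 0.04 in pool 2; edgeR adjusted p of 0.973). Over the alternatives that change ran from −0.10 to 0.39. Irf4 was higher in resting B cell-like cells than in the germinal centre classes, by 1.51 ± 0.27 (1.57 in pool 1 and 1.40 in pool 2; edgeR adjusted p of 6.79e-06). Dark zone-like cells held 29.0 CPM of Irf4 (23.3 to 35.6) in pool 1 and 40.1 (35.6 to 45.14) in pool 2, and light zone-like cells 32.7 (25.1 to 41.7) and 44.5 (38.6 to 51.0). Resting B cell-like cells held 74.98 (56.2 to 98.1) and 97.2 (74.4 to 125). Plasmablast-like cells held 117 (53.6 to 223) in pool 1 and 77.6 (16.0 to 227) in pool 2, from 9 and 3 Irf4 UMIs. Cells were also thinned to 1500 UMIs, and shallower cells were left out, unequally by class. Left out were 253 and 120 dark zone-like, 455 and 486 light zone-like and 13 and 7 resting B cell-like cells of pools 1 and 2. Irf4 was then found in 4.12% and 5.37% of dark zone-like, 4.63% and 6.96% of light zone-like and 8.67% and 11.6% of resting B cell-like cells. At that depth it was found in 1 of 90 T cell-like cells of pool 1, 1.11%, and in 0 of 130 cells of the unnamed class outside the germinal centre, which allows up to 2.31%. The interval of the T cell-like share, 0.0281% to 6.04%, overlapped those of all B cell classes of pool 1, such as 3.02% to 5.48% in dark zone-like, 3.097% to 6.62% in light zone-like and 0.471% to 6.50% in unnamed germinal centre cells. Pool 2 held 4 T cell-like cells at that depth, too few to measure its background.

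**Figure D4:**
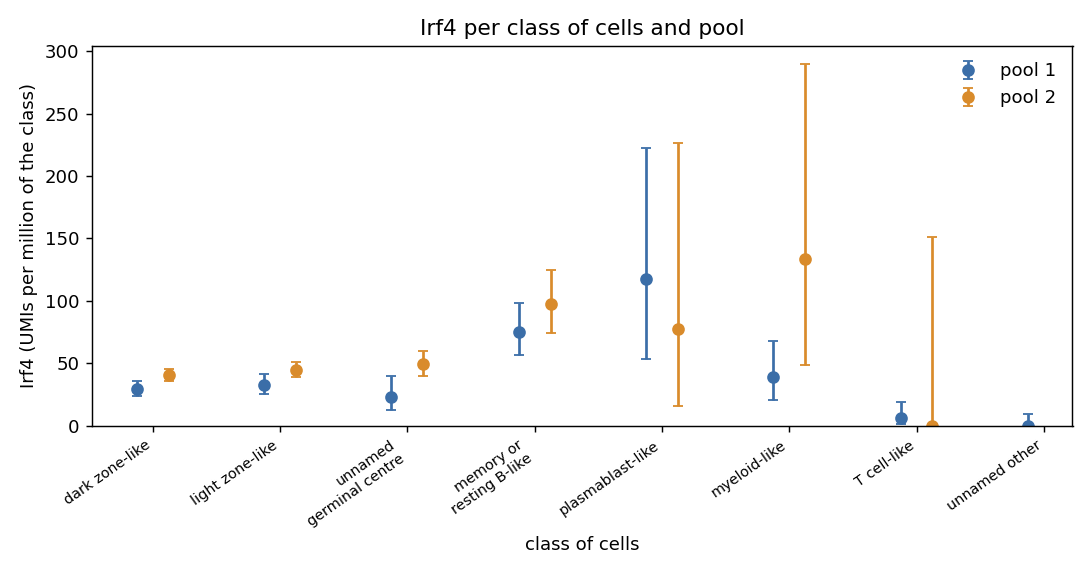
Irf4 CPM of each class, per pool, with 95% counting intervals. Dark zone-like and light zone-like cells lay between 29.0 and 44.5, and resting B cell-like cells at 74.98 in pool 1 and 97.2 in pool 2.

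Cells with and without an Irf4 UMI were compared to ask which genes went with Irf4 transcript within the B lineage, a split by a single transcript that is no genotype. In cells thinned to 1500 UMIs, 92 of 1993 cells of pool 1 (4.62%) and 263 of 4073 cells of pool 2 (6.46%) held Irf4. Iglc2 (ENSMUSG00000076937, chromosome 16, 19198396 to 19200351), a constant gene of the lambda light chain, was higher in cells with Irf4, by 0.96 ± 0.19 (1.08 in pool 1 and 0.82 in pool 2; edgeR adjusted p of 0.00643). With a mitochondrial limit of 5%, an alternative chosen in advance, its change was −1.10, and without the pool block the call was lost. It was the single gene past the test of 8702 tested; 0 genes fell, 541 had an unadjusted p under 0.05, and DESeq2 called 0 genes, with 48 at an unadjusted p under 0.05. The share of these cells whose Irf4 UMI came from free RNA is not known. Resting B cell-like cells, in which Iglc2 was also high, made up 15.2% of the cells with Irf4 in pool 1 and 6.84% in pool 2, against 7.15% and 3.15% of the cells without. In the germinal centre clusters alone the change in Iglc2 was 0.47 ± 0.33, and edgeR called 0 genes there, with 381 at an unadjusted p under 0.05. With the double precision clustering, Iglc2 was at 1.34 and edgeR called 21 genes.

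Of the fixed lists, 4 passed camera in this comparison, all with higher values in cells with Irf4. Of 25 Myc target and ribosome biogenesis genes, 0 passed edgeR and 1 when adjusted over the list alone, with a median of 0.28 and Pa2g4, a growth-regulated nucleolar protein, at 0.64 ± 0.20 (camera adjusted p of 9.12e-05; adjusted p = 0.764 with an estimated correlation). Of 13 genes of the NF-kB and CD40 response, 0 passed and 0 when adjusted over the list alone, with a median of 0.40 and Birc3, an inhibitor of cell death, at 0.52 ± 0.28 (camera adjusted p of 0.0200; adjusted p = 0.764 with an estimated correlation). Of 16 immediate early genes, 0 passed and 2 when adjusted over the list alone, with a median of 0.21 and Ier2 at 0.80 ± 0.23 (camera adjusted p of 0.0200; adjusted p = 0.764 with an estimated correlation). Of 24 ribosomal protein genes, 0 passed and 4 when adjusted over the list alone, with a median of 0.17 and Rpl10 at 0.47 ± 0.14 (camera adjusted p of 0.0192; adjusted p = 0.764 with an estimated correlation). With fry in place of camera, 0 lists passed. In the germinal centre clusters alone 3 of the 4 lists lost the call, and in dark zone-like cells 2 lost it and 2 changed sign. At a mitochondrial limit of 5% as well 2 lost it and 2 changed sign, and at 10% 3 lost it and 1 changed sign. The immediate early, NF-kB and ribosomal protein lists were also higher in resting B cell-like cells, which were more frequent among the cells with Irf4. The fit had 1 residual degree of freedom between pools. Without thinning, when cells with Irf4 are also deeper and 21.9% of those of pool 1 were resting B cell-like, 1374 genes were higher and 569 lower.

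Resting B cell-like cells were compared with the mean of the light zone-like and dark zone-like classes, a comparison added after the clusters were seen, to describe what set them apart from germinal centre cells. Serpinb1a, a protease inhibitor (ENSMUSG00000044734, mm10 chromosome 13, 32842092 to 32851185, protein-coding), was higher by 6.33 ± 0.32 on the log2 scale (SE, n = 2 pools; edgeR adjusted p of 9.42e-27), Notch2, a receptor of marginal zone B cell fate, by 4.39 ± 0.28, and Cmah, a sialic acid hydroxylase that germinal centre B cells lose, by 3.39 ± 0.27. The lambda light chain genes Iglc2 and Iglc1 were higher by 5.03 ± 0.32 and 3.39 ± 0.32, in a series whose sorted cells carried a knock-in receptor. Ifi203, Sdc4, Fam43a, Rpl10 and Snn were higher by 3.45 to 4.34. Lower were genes of replication and division, such as Uhrf1 by −3.34 ± 0.44, Kif15 by −3.30 ± 0.50, Birc5, survivin, by −3.22 ± 0.50, and Chaf1a, a chromatin assembly factor, by −3.13 ± 0.45. Clip2 was lower by −3.47 ± 0.48, and Kif23, Kif11, Knl1, Pola1 and Hells by −3.28 to −2.94. Of the constant genes, Ighm was higher by 3.33 ± 0.34 and Ighg1 lower by −2.40 ± 0.45, named after their values were seen. Of 8481 genes tested, 1512 were higher and 1098 lower in edgeR, with 3387 at an unadjusted p under 0.05, and DESeq2 called 1090 and 1189. The class was formed and named from these same counts, so many genes were bound to differ and the counts are no independent support. Erythroid markers were also higher in this class, 4 of 10 of them, with a mean log2 fold of 0.86. Of these, Hbb-bs, a haemoglobin gene singled out after its value was seen, had 288 UMIs in pool 2, all in 1 of 145 cells, and was found in 0 of 163 cells of pool 1. The median mitochondrial share was also lower in this class, at 4.10% in pool 1 and 11.8% in pool 2, against 21.3% and 27.0% in germinal centre cells. The median number of other UMIs was higher, at 3300 and 3364 against 1374 and 1527. No fit matched the classes on either measure, so how far RNA quality or depth shaped these genes and the lists below was not tested.

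By list, 11 of 19 passed camera in this comparison, 0 with an estimated correlation and 4 with fry in place of camera. Presentation genes rose: 8 of 13 for MHC class II, such as H2-Aa (2.70 ± 0.34), with 8 higher and 1 lower when adjusted over the list alone, and 7 of 13 for MHC class I, such as B2m (2.55 ± 0.31), with 7 when adjusted over the list alone. Their camera adjusted p-values were 0.000186 and 0.000156, each with adjusted p = 0.358 with an estimated correlation. Immediate early genes rose in 12 of 17 cases, such as Nr4a1 (2.62 ± 0.30) and Cd69 (2.44 ± 0.28), with 12 when adjusted over the list alone (camera adjusted p of 3.79e-07; adjusted p = 0.358 with an estimated correlation). Interferon response genes rose in 10 of 15 cases, such as Ifi203, with 10 higher and 1 lower when adjusted over the list alone (camera adjusted p of 3.45e-05; adjusted p = 0.379 with an estimated correlation). Genes of the NF-kB and CD40 response rose in 7 of 15 cases, such as Nfkb1 (1.02 ± 0.28), with 7 when adjusted over the list alone (camera adjusted p of 0.00194; adjusted p = 0.358 with an estimated correlation). Ribosomal protein genes rose in 21 of 24 cases, with 22 when adjusted over the list alone (camera adjusted p of 2.40e-13; adjusted p = 0.379 with an estimated correlation). Genes of oxidative phosphorylation rose in 17 of 25 cases, such as Uqcrb (2.56 ± 0.29), with 17 when adjusted over the list alone (camera adjusted p of 1.61e-05; adjusted p = 0.589 with an estimated correlation). Of 20 genes of secretion and the unfolded protein response 9 rose, such as Pdia4 (2.89 ± 0.26), and 1, Herpud1, named after its value was seen, fell, with the same counts when adjusted over the list alone (camera adjusted p of 0.000557; adjusted p = 0.358 with an estimated correlation).

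Most division genes fell in the same cells, as did 9 of 18 genes of somatic hypermutation and repair. Of 47 genes of the G2 and M phases 41 fell, with 42 when adjusted over the list alone (camera adjusted p of 3.31e-13; adjusted p = 0.379 with an estimated correlation). Of 40 genes of the S phase 32 fell, such as Mcm5, a subunit of the replicative helicase (−2.09 ± 0.35), with 34 when adjusted over the list alone (camera adjusted p of 4.26e-14; adjusted p = 0.358 with an estimated correlation). Of 18 genes of somatic hypermutation and repair 9 fell and 2 rose, with 10 and 2 when adjusted over the list alone. Among them were Rev1, a translesion polymerase (−1.86 ± 0.35), and Msh3, a mismatch repair protein (−1.03 ± 0.32), with a camera adjusted p of 0.00207 and an adjusted p = 0.358 with an estimated correlation.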

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

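All tests in this part were chosen after the result was seen. A group of 151 cells with high Crabp1 (ENSMUSG00000032291, mm10 chromosome 9, 54764748 to 54773110), a retinoic acid binding protein, made up 4.60% of the cells of pool 1 and 0 of the 4983 cells of pool 2, which allows up to 0.0602%, a class outside the comparisons above. Free RNA in the droplets was excluded as its source, since Crabp1 was found in 0 of the germinal centre cells of pool 1, an upper limit of 0.107%, and in 95.4% of the cells of the group. Doublets with a germinal centre B cell were excluded too, since Cd79a, a part of the B cell receptor, was at 10.2 CPM in the group against 793 CPM in germinal centre cells of that pool. Stroma in the sort, of which the gate on B220 and lysozyme binding should remove most, stays open: the mean log2 fold of the stroma and endothelium markers was 0.45, with Col3a1 at 63.6 CPM and Col1a1 at 2.54 CPM, against 6738 and 2007 CPM in the stroma-like cells of pool 2, while mitochondrial limits of 5% and 10% named all 151 cells stroma-like. The design names no biological explanation for a class in a single pool, and none was tested.

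Cells of types that the sort should have removed were present at levels above the limit that a count of 0 allows. T cell-like cells made up 2.80% of pool 1 and 0.0803% of pool 2. Myeloid-like cells made up 1.77% of pool 1 and 0.462% of pool 2. Stroma-like cells made up 0.221% of pool 2. Resting B cell-like cells made up 4.96% of pool 1 and 2.91% of pool 2. They were named by a list that holds Cd38, while the sort took CD38-low cells. Whether they met the gate or escaped it was not tested.

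Xist and genes on the Y chromosome set the pools apart. Xist, expressed from the inactive X chromosome, was found in 88.9% of the cells of pool 1 and in 0.0201% of the cells of pool 2. Genes on the Y chromosome were found in 43.1% of the cells of pool 2 and in 0.122% of the cells of pool 1, where Y-linked genes gave 4 UMIs. By these genes the cells of the pools differed in sex. The differences between the pools given above, in shares, isotypes and Crabp1-high cells, cannot be told apart from that difference.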

How the results depend on the processing

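The alternatives from the list of additions, named as added below, and the comparisons of resting B cell-like cells and of the Bcl2a1-high cluster were chosen after the data were seen. The resting B cell-like comparison stayed within 1.5 times its count under all 10 alternatives run, from 2149 to 3559 genes, and its change in Irf4 ran from 1.204 to 1.57. None of these alternatives matched the classes on depth or mitochondrial share, and in all of them the class was formed from the same counts that were tested. All other counts moved under some alternative, and for the values below the cause was not tested unless stated. Alternatives for the genotype comparison were not run, for want of a tag. Those for plasmablast-like cells were not run, except for at least 500 genes per cell and, both added, removal of the highest doublet scores and double precision, for want of cells. Keeping called doublets changed nothing, since none were called. Mitochondrial limits of 5% and 10% gave no zone comparison, with 0 dark zone-like cells at 5% and with 27 in pool 1 and 8 in pool 2 at 10%.

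With DESeq2 in place of edgeR, 176 genes differed between the zones (36 higher, 140 lower in the light zone-like class) and 0 by Irf4 UMI, with 48 at an unadjusted p under 0.05. With DESeq2 size factors, 2 genes differed by Irf4 UMI, and with no filter on low counts 5. Without the pool block, 135 genes differed between the zones and 0 by Irf4 UMI in edgeR, with 308 at an unadjusted p under 0.05. With an estimated correlation, the number of lists past the threshold was 0 in all 4 comparisons, and with fry it was 0 between the zones, 0 by Irf4 UMI, 4 for resting B cell-like cells and 5 for the Bcl2a1-high cluster; for the last pair these were added.

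With at least 500 genes per cell, the mean shares were 45.5% for dark zone-like, 33.9% for light zone-like and 0.837% for plasmablast-like cells, 673 genes differed between the zones and 6 by Irf4 UMI, and the zone change in Irf4 was −0.060. At a resolution of 0.5 the shares were 49.8% for dark zone-like, 41.6% for light zone-like and 4.72% for myeloid-like cells, with 0% for unnamed germinal centre, resting B cell-like and plasmablast-like cells, and at 1.2 the dark zone-like share was 47.4%. With each pool clustered on its own, the mean dark zone-like share was 33.6% (36.6% in pool 1 and 30.6% in pool 2). The mean light zone-like share was then 36.3% (29.6% and 42.9%) and the plasmablast-like share 0%.

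With cell cycle scores regressed out, run in double precision with exact neighbours, the shares were 34.5% for dark zone-like, 23.9% for light zone-like, 32.3% for unnamed germinal centre and 0% for plasmablast-like cells, and 1560 genes differed between the zones. The zone change reversed to −1.73 for C1qbp, −1.92 for Cox5a, −1.61 for Cox6c, −2.21 for Cycs, −1.10 for Eno1, −2.45 for Erh, −2.09 for Hspe1, −2.002 for Ndufa4, −2.21 for Nme1, −1.70 for Npm1, −0.21 for Pdia6, −0.17 for Psmb9, −1.36 for Rpl10, −1.30 for Rps2, −0.68 for Rps24, −0.87 for Rps27a, −2.03 for Rps27l, −1.50 for Sec61b, −1.08 for Sec61g and −1.33 for Srm. The median reversed to −0.45 for ribosomal proteins, −0.46 for Myc targets, −1.24 for oxidative phosphorylation and −0.21 for secretion. Of the Bcl2a1-high cluster, 215 cells were then dark zone-like and 68 light zone-like. Since the next alternative gave much the same reversals without regression, these cannot be put down to the regression. The unnamed germinal centre share was then 48.8% in pool 1 and 15.9% in pool 2, and with at least 500 genes 22.0% and 1.39%, against 11.96% and 20.3% without these choices.

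With double precision and exact neighbours in the clustering, an added alternative, 1331 of 8268 cells (16.1%) fell in another class, and the light zone-like share was 27.3%. Of the Bcl2a1-high cluster, 222 cells were then dark zone-like and 61 light zone-like. By Irf4 UMI, 21 genes differed, and between the zones 2476. The zone change reversed to −1.82 for C1qbp, −1.57 for Cox5a, −1.33 for Cox6c, −2.05 for Cycs, −0.69 for Eno1, −2.40 for Erh, −1.60 for Hspe1, −1.73 for Ndufa4, −2.01 for Nme1, −1.62 for Npm1, −0.32 for Pdia6, −0.00021 for Psmb9, −1.01 for Rpl10, −1.09 for Rps2, −0.40 for Rps24, −0.58 for Rps27a, −1.96 for Rps27l, −1.21 for Sec61b, −0.69 for Sec61g and −1.52 for Srm. The median reversed to −0.24 for ribosomal proteins, −0.90 for Myc targets, −1.13 for oxidative phosphorylation and −0.30 for secretion. The classes thus depended on numerical precision and the neighbour search, which were changed together and not told apart. They also depended on the resolution, where 2050 cells fell in another class at 0.5 and 953 at 1.2.

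Without the Bcl2a1-high cluster, an added alternative, 1375 genes differed between the zones, and the zone change reversed to −0.32 for C1qbp, −0.62 for Cox5a, −0.68 for Cox6c, −1.28 for Cycs, −0.89 for Erh, −0.66 for Hspe1, −1.08 for Ndufa4, −0.999 for Nme1, −0.66 for Npm1, −0.32 for Rpl10, −0.52 for Rps2, −0.20 for Rps24, −0.31 for Rps27a, −0.94 for Rps27l, −0.56 for Sec61b, −0.36 for Sec61g, −0.69 for Srm and −0.10 for Irf4. The median reversed to −0.15 for ribosomal proteins, −0.62 for Myc targets, −0.82 for oxidative phosphorylation and −0.15 for secretion. This alternative takes out the cells with the highest values of these genes in the class.

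Without the cycling dark zone-like clusters, also added, 69 genes differed between the zones. The change reversed to 0.42 for Cit, 0.33 for Esco2, 0.92 for Kif11 and 1.37 for Kif15. Cycling cells were taken out of the dark zone-like side only. The light zone-like side still held the Bcl2a1-high cluster, in which most G2 and M phase genes were higher than in other light zone-like cells. Under this alternative the median was 0.21 for the G2 and M phases, −0.028 for ribosomal proteins and −0.0036 for oxidative phosphorylation. With the zones fitted on their own libraries, added, 1078 genes differed. With the highest doublet scores removed, added, 970 genes differed between the zones and 7 by Irf4 UMI, and the light zone-like share was 29.9%. The resting B cell-like class of pool 2 then held 78 cells in place of 145, with double precision and exact neighbours 85 and at a mitochondrial limit of 30% 68. With mitochondrial and ribosomal RNA genes left out, added, the zone change in Irf4 was −0.016.

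With a mitochondrial limit of 5%, the shares were 0% for dark zone-like, 9.40% for T cell-like, 23.4% for light zone-like, 16.7% for resting B cell-like, 4.99% for myeloid-like, 6.15% for plasmablast-like and 9.18% for unnamed germinal centre cells, with 35.2% of pool 1 named stroma-like, and 32.3% for Ighg2b, 4.29% for Ighg2c and 3.04% for Ighm. By Irf4 UMI, 2 genes differed, with −0.043 for Cd69, −0.86 for Ier2, −1.10 for Iglc2, −0.38 for Jun, −0.27 for Rps2 and −0.053 for Rps24, and with medians of −0.37 for immediate early genes and −0.012 for Myc targets. At 10%, added, the shares were 7.46% for T cell-like, 3.57% for dark zone-like, 20.4% for resting B cell-like, 4.28% for myeloid-like and 4.402% for plasmablast-like cells, with 23.8% of pool 1 named stroma-like, and 36.6% for Ighg2b, and by Irf4 UMI the change was −0.093 for Ier2, −0.66 for Nop58, −0.46 for Pa2g4 and −1.02 for Relb, with a median of −0.27 for Myc targets. At 30%, added, the shares were 46.1% for dark zone-like, 32.7% for light zone-like, 2.10% for myeloid-like and 0% for plasmablast-like cells and 32.1% for Ighg2b, and 0 genes differed by Irf4 UMI in edgeR, with 361 at an unadjusted p under 0.05.

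By Irf4 UMI, another thinning seed gave 9 genes and −0.13 for Relb, and 4 genes differed at 750 UMIs, with −0.12 for Birc3, −0.13 for Pa2g4 and −0.11 for Rrs1. Without thinning 1943 genes differed, and with at least 2 Irf4 UMIs 1971. Depth, the return of shallow cells and the resting B cell-like share of cells with Irf4, 21.9% and 33.3% in pool 1 against 15.2% with thinning, were not separated there. In dark zone-like cells 0 genes differed in edgeR, with 276 at an unadjusted p under 0.05, and the change was −0.40 for Birc3, −0.29 for Ier2, −0.47 for Nop58, −0.58 for Pa2g4 and −0.26 for Rel, with medians of −0.041 for the NF-kB list and −0.054 for immediate early genes. In light zone-like cells 4 genes differed, with −0.34 for Jun, −0.25 for Rpl10, −0.14 for Rps24 and a median of −0.068 for ribosomal proteins. In germinal centre clusters, added, 0 genes differed in edgeR, with 381 at an unadjusted p under 0.05.

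Leaving out each replicate in turn, which leaves values with no test, the change by Irf4 UMI ran from −0.24 to 0.99 for Jun, from −0.065 to 1.02 for Dkc1 and from −0.17 to 0.42 for Rel, and the median of B cell receptor signalling between the zones from −0.0017 to 0.34. Of the other results left out in this way, none changed direction. At 2000 to 6000 UMIs, added, 666 genes differed for the Bcl2a1-high cluster. With an isotype minimum of 1 UMI, the mean shares were 51.6% for Ighg1, 32.6% for Ighg2b and 5.22% for Ighg2c, with 10 UMIs 71.4%, 21.9% and 0.888%, and at 90% purity that of Ighg2b was 29.9%.

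Other results are given as counts. Of 49 genes named between the zones, 13 kept their direction but lost significance with DESeq2, 13 without the block and 15 without the cycling clusters. Of the same genes, 10 gained it with the highest doublet scores removed, 9 with cell cycle regression, and 13 each with double precision and on the zones' own libraries. With cell cycle regression and with double precision, 20 reversed. Of the 10 lists past the threshold there, 3 lost it without the cycling clusters. Of 17 genes named by Irf4 UMI, 12 gained significance without thinning and 13 with at least 2 Irf4 UMIs, and of the 4 lists 3 lost it in germinal centre clusters and 2 each without thinning, with at least 2 Irf4 UMIs and at 750 UMIs. None of the 4 kept it at mitochondrial limits of 5%, where 2 reversed, and 10%, where 1 reversed, or in dark zone-like cells, where 2 reversed. Of 55 genes named for resting B cell-like cells, at most 1 lost it under any alternative, and of 53 tested for the Bcl2a1-high cluster 8 lost it at 2000 to 6000 UMIs, as did 2 of the 10 lists. Without replicate 1, 31 of the 55 moved by more than the SE, and 24 without replicate 2, and of 56 named for the Bcl2a1-high cluster 20 and 23 did.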

Other observations

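The comparison in the next paragraphs and the tests of RNA loss in other light zone-like cells, of doublets among germinal centre cells, of free mitochondrial RNA and of damage to a whole library were chosen after the results were seen, and the second test of free mitochondrial RNA was added after the first had left it open. Within the light zone-like class a cluster with high Bcl2a1b and Bcl2a1d had a profile of growth and division, with 33 cells in pool 1 and 250 in pool 2. Against the other light zone-like cells, Ccna2, cyclin A, was higher by 5.96 ± 0.41 on the log2 scale (SE, n = 2 pools), Birc5, survivin, by 5.85 ± 0.35, Rrm2, a subunit of ribonucleotide reductase, by 5.00 ± 0.33, Nme1 by 4.68 ± 0.24, and Cdc20, an activator of the anaphase-promoting complex, by 4.64 ± 0.35. Cks1b, Ppa1, Erh, Nme2 and Tomm5 were higher by 4.60 to 5.45. H2-Ob, a regulator of class II peptide loading, was lower by −2.26 ± 0.22. AL732506.1 was lower by −3.94 ± 0.38, and Slc12a3, Adcy7, Dennd1c, Abcb10, Abca7, Rasa3 and Tcirg1 by −2.68 to −2.25. Irf4 was higher by 0.78 ± 0.29 (1.62 in pool 1 and 0.40 in pool 2; edgeR adjusted p of 0.0187). Of 8319 genes tested, 2317 were higher and 1866 lower in edgeR, in a cluster that was deeper than its comparator. With mitochondrial and ribosomal RNA genes left out, an added alternative, 2109 were higher and 2202 lower of 8333. The cluster was formed from the same counts and picked by its Bcl2a1b level, so many genes were bound to differ and these counts are no independent support. The fit had 1 residual degree of freedom between pools. At 2000 to 6000 UMIs, an added alternative, 436 were higher and 230 lower of 5658. Of the light zone markers, 11 of 15 were raised in this cluster, 5 of 15 dark zone markers and 5 of 14 plasmablast markers.

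By list, 10 of 19 passed camera in this comparison and 0 with an estimated correlation. With fry in place of camera, 3 of these 10 passed, ribosomal proteins, glycolysis and immediate early genes, and 2 others, mTORC1 and amino acid uptake and somatic hypermutation and repair. At 2000 to 6000 UMIs, 8 of the 10 kept the camera call, and the S phase and secretion lists lost it. Higher were 24 of 25 Myc target and ribosome biogenesis genes, such as C1qbp (4.25 ± 0.24) and Srm (4.08 ± 0.25), with 24 when adjusted over the list alone (camera adjusted p of 1.50e-10; adjusted p = 0.467 with an estimated correlation). All 25 genes of oxidative phosphorylation were higher, such as Uqcrb (4.39 ± 0.28), with 25 when adjusted over the list alone (camera adjusted p of 2.09e-11; adjusted p = 0.467 with an estimated correlation). All 24 ribosomal protein genes were higher, with 24 when adjusted over the list alone (camera adjusted p of 1.95e-08; adjusted p = 0.467 with an estimated correlation). Of 47 genes of the G2 and M phases 39 were higher, with 39 when adjusted over the list alone (camera adjusted p of 7.48e-13; adjusted p = 0.467 with an estimated correlation), and of 40 genes of the S phase 32, with 32 when adjusted over the list alone (camera adjusted p of 4.23e-09; adjusted p = 0.624 with an estimated correlation). Of 14 glycolysis genes 9 were higher, such as Ldha (2.42 ± 0.20), and 1, Hk2, named after its value was seen, lower, with 10 and 1 when adjusted over the list alone (camera adjusted p of 0.00341; adjusted p = 0.467 with an estimated correlation). Of 20 genes of secretion and the unfolded protein response 15 were higher and 1 lower, with the same counts when adjusted over the list alone (camera adjusted p of 0.000984; adjusted p = 0.467 with an estimated correlation). Of 7 heat shock genes 6 were higher, such as Hspa8 (1.77 ± 0.16), with 6 when adjusted over the list alone (camera adjusted p of 0.0291; adjusted p = 0.653 with an estimated correlation). Lower were 17 of 18 genes of B cell receptor signalling, such as Cd22 (−2.14 ± 0.19) and Lyn (−1.35 ± 0.22), with 17 when adjusted over the list alone (camera adjusted p of 5.90e-05; adjusted p = 0.467 with an estimated correlation), and 13 of 16 immediate early genes, such as Egr1 (−1.66 ± 0.21), with 13 when adjusted over the list alone (camera adjusted p of 0.000166; adjusted p = 0.467 with an estimated correlation).

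Loss of cytoplasmic RNA from the other light zone-like cells stays open as a source of the higher Myc target list in this cluster. Among cells of at most 15% mitochondrial UMIs the median log2 difference of the list was 2.46 (2.47 in pool 1 and 2.73 in pool 2). This limit did not make both sides alike. The other light zone-like cells then had medians of 1516 and 1426 UMIs and mitochondrial shares of 11.7% and 11.3% in pools 1 and 2. The cluster had 3140 and 8082 UMIs and shares of 7.17% and 9.42%. A doublet of light zone-like and other germinal centre cells, each at the average level of its cluster, cannot exceed the higher of both clusters. The median log2 ratio of the list to the highest other germinal centre cluster was 1.39 in pool 1 and 1.11 in pool 2, with 24 of 25 genes above it in both. These values argue against doublets of such average cells. Doublets of cells far above the average of their cluster could not be excluded in this way. Doublets with a cell of another class stay open, since that ratio to the highest cluster of any class was 0.363 in pool 1 and 1.11 in pool 2. Depth stays open as well, since the cluster had medians of 2841 and 5901.5 UMIs against 1578 and 1697, and at 2000 to 6000 UMIs the median difference was 1.37 over both pools but 0.62 in pool 1, where 14 cells of the cluster were left. No biological explanation was tested, since the genotype of the cells is not given.

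The mitochondrial share of germinal centre cells, a median of 21.3% in pool 1 and 27.0% in pool 2, was far above that of resting B cell-like cells. Damage that reached all cells of a library alike could not be excluded. The share in germinal centre cells was 5.19 times that in resting B cell-like cells in pool 1 and 2.28 times in pool 2. Such ratios speak against like damage only if both cell types had like shares before it, which is not known. The share in resting B cell-like cells itself differed between the libraries, at 4.10% in pool 1 and 11.8% in pool 2. Free mitochondrial RNA was left open by a first test, in which germinal centre cells of pool 1 held 2.22 times the mitochondrial UMIs of T cell-like cells, and a second test, added because of that, argued against it as the whole cause: germinal centre cells held 6.36 times in pool 1 and 18.7 times in pool 2 the mitochondrial UMIs of the class with the fewest, which bounds what free RNA adds. Loss of cytoplasmic RNA from germinal centre cells stays open, with a Spearman correlation of −0.0626 in pool 2 and −0.178 in pool 1, over cells rather than independent samples, between the mitochondrial share and the number of other UMIs. No biological explanation was tested.

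The planned comparison of plasmablast-like cells could not be run with 23 and 17 cells. With at least 500 genes per cell, the class held 35 and 28 cells, and 1013 genes were higher and 776 lower of 8344 tested in edgeR than in the germinal centre classes. Irf4 was then higher by 1.47 ± 0.36 (edgeR adjusted p of 0.00237). The plasmablast-like class grew although the filter was stricter, while myeloid-like cells fell from 58 and 23 to 34 and 1. Its members had thus changed, and whether the higher Irf4 came from plasmablast-like cells was not tested. In the plasmablast-like class of this setting Ccl3 was at 327 and 140 CPM and Ccl4 at 366 and 356 CPM in pools 1 and 2. Cd209a was at 125 and 279 CPM and Fyb at 246 and 63.5 CPM. All were at 1.45 CPM or less in both zones. These genes, singled out after their values were seen, are known from other cell types. Whether their transcripts came from other cells was not tested. With the highest doublet scores removed, an added alternative, 293 genes were higher and 607 lower of 8240 tested. With double precision and exact neighbours in the clustering, also added, 365 were higher and 437 lower of 8228.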
